A study of Homo sapiens with 9 samples.

How the data were processed

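Polyadenylated RNA was sequenced from MDA-MB-231, a triple-negative breast cancer cell line, in 9 libraries. Per the labels, 3 libraries came from cells given DMSO (time labelled 12 h), 3 from cells given 3.3 µM indisulam for 12 h and 3 from cells given 10 nM pladienolide B for 6 h. RNA was purified on silica columns with DNase and made into libraries with a stranded mRNA kit (library type fr-secondstrand), per the labels' protocols. The submitters' processing notes name FastQC, Picard, SAMtools, STAR 2.7.5a, DESeq2 and the genome build hg38, per the labels. The counting tool and its strand setting are not given in the sources used here.

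The deposited table held a signal per feature and library: read counts divided by 1 size factor per library, by the authors with DESeq2, per the name of the deposited table and the labels. It listed 46846 features with FAST DB identifiers, of which 25854 carried a symbol and 46084 carried hg38 coordinates. The columns of all 9 libraries were assigned to groups by name. In each library all values came out as whole multiples of the value of 1 read (100% within a tolerance of 0.01), so whole reads were recovered. In the library labelled pladienolide B replicate 1 that value was 1.00. Size factors that DESeq2 gave from the recovered reads were 1.03 times the deposited ones in every library. The libraries held between 59312100 and 83910831 reads. A count of 3 reads, the upper limit that 0 reads allows, corresponded to deposited values of 2.48 to 3.87, and such limits cover counting error only.

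Since the values were normalised, the main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with a mean per group, all 9 libraries in 1 fit, moderated variances with a mean trend, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Genes with a mean value of at least 10 over the 9 libraries were tested, 16846 in all, 14288 of them with a symbol. The comparisons were each drug against DMSO and the drugs against each other. The labels call the libraries of a group replicas and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries. No pair of libraries agreed within sampling noise: the lowest chi-square per gene between libraries of 1 group was 9.45. The fit was tested on simulated data of 16846 genes, with 50 genes changed at each fold. For indisulam it recovered 8% of genes changed 1.25-fold, 42% at 1.5-fold, 72% at 2-fold and 92% at 4-fold. The same shares for pladienolide B were 12%, 62%, 82% and 96%. Of all calls, 9 of 116 and 2 of 128 were false. Far fewer genes changed there than were called in the data (4532 and 11752), and the adjusted threshold depends on that number. The shares are thus not the sensitivity of the real comparisons. Both runs used the DMSO means and the same dispersions, so differences between the drugs come from random draws and read depth.

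Before the data were examined, 28 gene lists, the comparisons, the alternatives and the rule for the genes named in the text were fixed. The lists cover splicing factors (the SF3b and U2 snRNP proteins, RBM39 with its DCAF15 ligase, SR proteins with their kinases, hnRNPs), DNA repair, replication and mitosis, p53, BCL2 family and stress genes, immediate early, MAPK, NF-kB and interferon genes. They also cover cholesterol synthesis, glycolysis, ribosome biogenesis, ribosomal proteins, histones, intronless genes, targets of nonsense-mediated decay (NMD), extracellular matrix genes, mitochondrial transcripts, and markers of luminal epithelium and leukocytes. Of 809 list memberships, 771 were matched to a feature by symbol or older symbol. The mitochondrial list had no matching symbols, and features on the mitochondrial chromosome were used in its place, a choice made after seeing the data. These features are stretches of that chromosome and not single genes. GSHG0045380 spans positions 5584 to 12142, and the short GSHG0045390 (11945 to 11969) lies within that span. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. No list call in any of the 3 comparisons held with an estimated correlation. Members were also adjusted over the list alone.

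The genes named are, for each drug, the 10 with the largest rise and the 10 with the largest fall among genes with a symbol, an adjusted p under 0.05, a mean of at least 100 and no overlap between the 3 treated and 3 DMSO values (6 per direction between the drugs). SF3B1, PHF5A, RBM39, RBM23, DCAF15, MYC, MCL1 and CDKN1A were named whatever their values, as were, for each drug, up to 2 called members per list and direction with the largest fold change (where none was called, the member with the highest mean). Some genes that the rule names are not reported here. Of 211 named genes with coordinates, 81 overlapped another tested feature, and without a stated strand setting their reads cannot be told apart from those of the overlapping feature.

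The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM scaling, the same total per library, quantile normalisation, the replicate number as a block, no variance trend, the 2 groups alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Protein-coding genes by RefSeq symbol were added after the data were seen, since the table gives no biotype and the planned restriction could not be run as written. Features were matched to GENCODE v29 on the same build by symbol and position for tests of gene structure, and 94.6% of tested symbols had a match. Tables were joined, permutation tests run and plots drawn with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.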

Results

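RNA was measured in MDA-MB-231, a human triple-negative breast cancer cell line, after treatment with either of a pair of drugs that act on splicing by different routes. Indisulam is a sulfonamide that recruits the splicing factor RBM39 to the DCAF15 ubiquitin ligase for degradation. Pladienolide B binds the SF3b complex of the U2 snRNP, which recognises the branch site of introns. There were 3 libraries each of DMSO (12 h), indisulam (3.3 µM, 12 h) and pladienolide B (10 nM, 6 h).

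The DMSO libraries held 72847579, 74627193 and 59312100 reads, the indisulam libraries 68666341, 62823691 and 60733086, and the pladienolide B libraries 83910831, 67853212 and 64936378. After the authors' normalisation the totals were 61016460 ± 574381 in DMSO, 63349449 ± 409132 with indisulam and 84689853 ± 2607968 with pladienolide B (mean ± SD, n = 3), a ratio of 1.39 between pladienolide B and DMSO. Reads on the mitochondrial chromosome made up 8.72 ± 0.437% in DMSO, 9.93 ± 0.189% with indisulam and 13.8 ± 0.150% with pladienolide B (SD, n = 3). The 100 highest features held 27.1%, 28.3% and 35.3% of the signal in the same order. Each drug differed from DMSO in these 3 measures with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give.

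**Figure D1:**
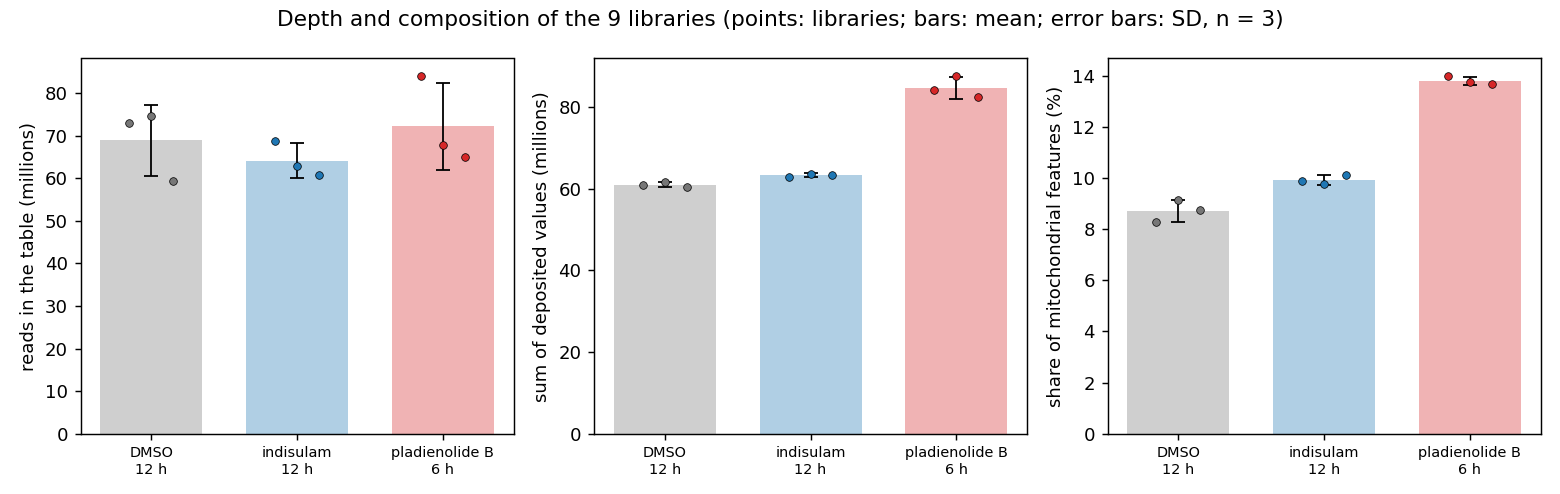
Depth and composition of the 9 libraries, with points for libraries, bars for means and error bars for the SD (n = 3). The mitochondrial share was 13.8% with pladienolide B and 8.72% in DMSO, and the deposited totals were highest with pladienolide B.

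The comparison of indisulam with DMSO asked how transcript levels stood after 12 h of a drug that removes RBM39. The transcript of RBM39 itself (GSHG0027334, hg38 chromosome 20, 35701347 to 35742260) rose from 15036 ± 392 to 37646 ± 950 (SD, n = 3; log2 fold change 1.32 ± 0.05, where ± beside a log2 value is the SE; limma adjusted p = 1.86e-08). POLE2, a subunit of DNA polymerase epsilon, fell by 1.17 on the log2 scale, and TOP2A, the topoisomerase of mitotic chromosomes, fell by 1.14. POLE2 (mean 1724 over the 9 libraries) overlaps RPS29 (mean 23541), and without a stated strand setting their reads cannot be told apart. The same holds for other genes named below that overlap a feature with a higher mean. Among them are RBM23 with DAD1, BAX and PPP1R15A with FTL, and CDC25C with FAM53C.

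In all, 2437 of 16846 genes rose and 2095 fell with indisulam at a limma adjusted p under 0.05, of which 366 and 248 changed at least 2-fold. These 614 compare with 381 at a mean of at least 50 and 212 among protein-coding symbols, where fewer genes were tested. The number tested alone does not account for the 212, since 12405 of the 16846 genes matched protein-coding genes of GENCODE. Over all 16846 genes the 3 treated values did not overlap the 3 DMSO values in 8152 (48.4%), a separation that chance gives in 10% of genes. The count of higher genes was 1620 without DMSO replicate 2 and 1565 without indisulam replicate 3. The higher genes made up 53.8% of the changed genes as deposited, 42.5% with TMM scaling and 40.3% with the same total per library.

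Among genes of the RBM39 and DCAF15 ligase list, 4 of 11 rose, none fell and 7 did not pass (5 rose when adjusted over the list alone; camera adjusted p = 0.0224). The list's adjusted p = 0.727 with an estimated correlation, and the call was lost with the same total per library (0.0625) and with quantile normalisation (0.0536). RBM23, the paralog of RBM39 and a substrate of the same ligase (GSHG0012733, chromosome 14, 22893204 to 22919165), rose from 3512 ± 149 to 4875 ± 60.0 (0.47 ± 0.06, limma adjusted p = 0.000115). DCAF15, the substrate receptor (GSHG0021236, chromosome 19, 13952474 to 13961448), stood at 3109 ± 115 in DMSO and 3179 ± 55.1 with indisulam (0.03 ± 0.07, adjusted p = 0.786).

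SF3B1, the SF3b subunit with recurrent mutations in cancer (GSHG0026214, chromosome 2, 197389785 to 197435093), rose from 11330 ± 502 to 14943 ± 74.2 (0.40 ± 0.06, limma adjusted p = 0.00023). Of the SF3b and U2 snRNP list, 7 of 20 genes rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.287). SF1, which binds the branch point, rose by 0.60, and SUGP1, an SF3B1 partner, fell by 0.64 on the log2 scale. PHF5A, a small SF3b subunit (GSHG0029290, chromosome 22, 41459717 to 41468692), was at 1231 ± 45.5 and 1499 ± 87.0 (0.28 ± 0.10, limma adjusted p = 0.0429). That call was lost in 10 alternatives, among them TMM scaling, the same total per library and leaving out any 1 library of the groups compared, with adjusted p from 0.00598 to 0.146.

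Of the SR proteins and their kinases, 12 of 22 rose and 2 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.0051; adjusted p = 0.727 with an estimated correlation). CLK4, a kinase of SR proteins, rose by 0.98 and SRRM1, a splicing coactivator, by 0.92, while SRSF6 fell by 0.55 on the log2 scale. Of the hnRNPs, 8 of 19 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0399, adjusted p = 0.786 with an estimated correlation). PTBP2 rose by 0.93 and HNRNPDL by 0.62, and HNRNPU fell by 0.23. The hnRNP call was lost with TMM scaling (adjusted p = 0.0809), the same total (0.0802) and quantile normalisation (0.114), with a mean of at least 50 (0.0573), and without indisulam replicate 2 (0.0850).

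Targets of nonsense-mediated decay (NMD) gave the highest median among the lists: 11 of 19 rose and none fell, with the same counts adjusted over the list alone (median 0.42, camera adjusted p = 0.000212; adjusted p = 0.727 with an estimated correlation). The snoRNA host genes SNHG1 and SNHG16 rose by 0.94 and 0.84. Of the intronless genes, 13 of 35 rose and none fell (15 and 0 adjusted over the list alone; camera adjusted p = 0.00811, adjusted p = 0.786 with an estimated correlation), among them CHMP1B, an ESCRT subunit, by 0.61. Of the immediate early genes, 11 of 32 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00811, adjusted p = 0.786 with an estimated correlation). The phosphatase gene DUSP1 rose by 0.86 and NR4A2 by 1.26, while IER3 fell by 0.27. MYC (GSHG0042006, chromosome 8, 127735434 to 127742951) rose from 5730 ± 167 to 6976 ± 69.2 (0.28 ± 0.05, limma adjusted p = 0.00147). The immediate early call was lost without DMSO replicate 1 (adjusted p = 0.0553).

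Of the DNA replication genes, 17 of 39 fell and 2 rose (18 and 3 adjusted over the list alone; camera adjusted p = 0.000171, adjusted p = 0.786 with an estimated correlation). CDC45, part of the replicative helicase, fell by 0.99 and the origin subunit gene ORC6 rose by 0.67. Of the homologous recombination and Fanconi anemia genes, 10 of 36 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.786 with an estimated correlation). FANCL, a ubiquitin ligase, fell by 1.09 and the nuclease gene MUS81 by 0.93. Of the mitotic genes, 17 of 54 fell and 7 rose (19 and 7 adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.902 with an estimated correlation). The condensin subunit gene NCAPG fell by 1.15 and KIF23, a kinesin of cytokinesis, rose by 0.37. The mitotic call was lost without DMSO replicate 1 (adjusted p = 0.0772), indisulam replicate 3 (0.0987) or pladienolide B replicate 3 (0.0590) and with a mean of at least 50 (0.0573).

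Ribosomal protein genes moved little: 3 of 54 rose and 2 fell (1 and 0 adjusted over the list alone; median 0.09, camera adjusted p = 0.0025, adjusted p = 0.902 with an estimated correlation), and the call was lost with quantile normalisation (0.141). RPL21 rose by 0.59. Of the chaperone genes, 6 of 20 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0457, adjusted p = 0.786 with an estimated correlation), with HSPA1B, an inducible HSP70, up by 0.58. That call was lost in each of the 3 scalings, with a mean of at least 50 (adjusted p = 0.0702) and without DMSO replicate 2 (adjusted p = 0.124), DMSO replicate 3 (0.0615) or indisulam replicate 3 (0.0723). Of 15 mitochondrial features tested, 5 rose and none fell, and 2 rose with TMM scaling.

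The other lists did not pass camera with indisulam. Of the checkpoint genes, 4 of 22 rose and 8 fell (6 and 9 adjusted over the list alone), with ATR, the kinase of stalled forks, at −1.02. Of the excision repair genes, 1 of 23 rose and 6 fell, with LIG3, a DNA ligase, at −1.05. Of the p53 targets, 6 of 28 rose and 6 fell, with CCNG1 at 0.79 and FDXR at −0.71. CDKN1A, the p21 inhibitor of cyclin-dependent kinases (GSHG0036715, chromosome 6, 36676463 to 36687332), was at 4147 ± 295 and 3461 ± 363, with overlapping values (−0.26 ± 0.09, limma adjusted p = 0.036). That call was lost without DMSO replicate 1 or 2 or indisulam replicate 1 or 3, and its adjusted p ranged from 0.00318 to 0.152. Of the BCL2 family and apoptosis genes, 4 of 27 rose and 2 fell, with CASP2 at 0.64 and BAX at −0.28. MCL1, an antiapoptotic member (GSHG0002983, chromosome 1, 150574554 to 150579610), rose from 29478 ± 151 to 34304 ± 324 (0.22 ± 0.05, limma adjusted p = 0.00316).

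Of the stress response genes, 3 of 29 rose and 4 fell (3 and 3 adjusted over the list alone), with PPP1R15A, a phosphatase subunit, at 0.48. Of the MAPK genes, 6 of 21 rose and 4 fell (7 and 5 adjusted over the list alone), with SPRED3 at −1.07. Of 23 NF-kB genes none rose in limma (5 at an unadjusted p under 0.05, 1 in edgeR and 3 in DESeq2) and 1 fell, LIF, by 0.23, a call lost without DMSO replicate 1 or 2 or indisulam replicate 3. Of the interferon genes 1 of 25 rose and 6 fell, with MX2 at −0.93, and the list passed without DMSO replicate 2 (adjusted p = 0.0487) or indisulam replicate 1 (0.0489). Of the cholesterol genes, 2 of 23 rose and 3 fell, with HMGCS1 at 0.70 and HSD17B7 at −0.81. Of the glycolysis and hypoxia genes, 3 of 29 rose and 1 fell (1 and 1 adjusted over the list alone), with the peptide hormone gene ADM at 0.75, and 1 was higher and 5 lower with the same total. Of the ribosome biogenesis genes, 1 of 29 rose and 3 fell (1 and 1 adjusted over the list alone), with UTP4 at −0.74, and the list passed without DMSO replicate 1 (adjusted p = 0.0491) or indisulam replicate 3 (0.0375).

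Of the extracellular matrix genes, 6 of 36 rose and 7 fell, with CCN2 at 0.69 and the integrin gene ITGA2 at −0.60. None of 34 histone genes passed in limma, where 1 was higher and 3 were lower at an unadjusted p under 0.05; edgeR called none and DESeq2 called 1 higher. H2BC12, the histone gene with the highest mean, was at 0.11 ± 0.06 (limma adjusted p = 0.164). The libraries were made from polyadenylated RNA, so histone transcripts without a poly(A) tail were not measured. Of the luminal genes 1 of 13 rose and 2 fell, with GATA3 at 0.38 and MLPH at −0.41, and of 8 leukocyte genes CSF1R alone passed, at −1.07. For the excision repair, p53, BCL2, NF-kB, interferon, cholesterol, matrix, luminal and leukocyte lists the counts were the same when adjusted over the list alone.

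The genes with the largest rise with indisulam included GUCA1B, a guanylate cyclase activator of photoreceptors (3.16 ± 0.27), DCAF4L1 (2.44 ± 0.27) and RSRP1, which encodes an arginine and serine rich protein (2.17 ± 0.09). The largest falls included the long noncoding RNA MANCR (−2.43 ± 0.11), MYH3, an embryonic myosin (−1.99 ± 0.26), and CYP4V2, a fatty acid hydroxylase (−1.84 ± 0.13). TNRC18P1 (near the floor of 3 reads in DMSO) and FBXW4P1 (1.83 ± 0.35) rose and LOC399975 (−2.58 ± 0.19) fell, and these 3 lie within TBC1D9, BCR and ARHGAP32, and their reads were not separated from those of these genes.

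The comparison of pladienolide B with DMSO asked how transcript levels stood under an SF3b inhibitor, at 6 h against 12 h of DMSO. MYC was 5.79-fold higher, at 33215 ± 1476 against 5730 ± 167 (SD, n = 3; 2.53 ± 0.05, limma adjusted p = 3.76e-12). All 54 ribosomal protein genes tested rose, as did most immediate early genes. CDKN1A fell from 4147 ± 295 to 933 ± 50.7 (−2.15 ± 0.09, adjusted p = 1.43e-10), and most mitotic and homologous recombination genes fell. SF3B1, whose protein is the target's core, rose to 18833 ± 1132 (0.73 ± 0.06, adjusted p = 6.34e-08).

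With pladienolide B 5776 genes rose and 5976 fell at a limma adjusted p under 0.05, of which 1620 and 3017 changed at least 2-fold (4637 together, against 2931 among protein-coding symbols). Over all genes tested the values did not overlap in 12091 (71.8%), against 10% by chance. With the same total per library 2733 rose and 9086 fell, and that scaling moved the median of all genes by −0.47 and called 520 genes in the opposite direction; TMM scaling moved the median by −0.10. Drug and time differed together in this comparison.

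PHF5A rose to 2030 ± 273 (0.71 ± 0.10, limma adjusted p = 1.38e-05). Of the SF3b and U2 snRNP list, 12 of 20 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.168), and its median of 0.29 was −0.18 with the same total and −0.02 with quantile normalisation. SF3B5 rose by 1.11 and SF3B6 by 0.86, while the helicase gene DDX42 fell by 2.08 on the log2 scale. RBM39 stood at 18292 ± 848 (0.28 ± 0.05, adjusted p = 0.000247), but at −0.19 with the same total and −0.13 with quantile normalisation. DCAF15 fell to 938 ± 77 (−1.73 ± 0.07, adjusted p = 2.42e-10) and RBM23 to 1488 ± 48.4 (−1.24 ± 0.06, adjusted p = 9.3e-10). Of the ligase list 5 of 11 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.994).

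Of the hnRNPs, 16 of 19 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.473 with an estimated correlation). HNRNPDL rose by 1.62 and HNRNPA0 by 1.18, while PTBP3 fell by 1.34 on the log2 scale; the list's median of 0.56 was 0.08 with the same total, where 6 genes were higher and 5 lower, and the call was lost with quantile normalisation (adjusted p = 0.648). Of the SR proteins and kinases, 13 of 22 rose and 6 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.0735), with a median of 0.29 that was −0.19 with the same total, and the list passed without the filter (0.0287). SRSF3 rose by 1.53 and SRSF2 by 1.49, and the kinase gene CLK2 fell by 1.52.

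All 54 ribosomal protein genes rose, the same adjusted over the list alone (median 0.90, camera adjusted p = 8.1e-22; adjusted p = 0.473 with an estimated correlation), with RPL21 at 1.23. All 54 were also higher with the same total per library (median 0.43), and 44 with quantile normalisation. All 15 mitochondrial features rose (median 1.09), 11 of them also with the same total. They are long and short stretches that partly overlap, so their number is not a number of separate transcripts. Of the histone genes, 25 of 34 rose and none fell (26 and 0 adjusted over the list alone; camera adjusted p = 0.000664, adjusted p = 0.473 with an estimated correlation), with H2BC21 at 1.28. The histone median of 0.86 was 0.40 with the same total per library, where 9 genes were higher. Since polyadenylated RNA was sequenced, these values do not give the level of histone transcripts without a poly(A) tail. The mitochondrial share of reads was 13.8% in these libraries and 8.72% in DMSO.

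Of the immediate early genes, 24 of 32 rose and 5 fell, the same adjusted over the list alone (median 0.99, camera adjusted p = 0.000664; adjusted p = 0.576 with an estimated correlation). CCN1, a matricellular protein gene, rose by 2.48, and BTG2, an antiproliferative gene, fell by 2.05 on the log2 scale. Of these genes 16 were higher and 7 lower with the same total per library. Of the intronless genes, 23 of 35 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.00155; adjusted p = 0.576 with an estimated correlation), and the median of 0.40 was −0.07 with the same total, where 11 were higher and 10 lower. CEBPD rose by 2.35 and RRS1, a ribosome assembly gene, by 1.88. Of the NMD targets, 13 of 19 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.576 with an estimated correlation). GADD45B rose by 2.65 and SNHG15 by 2.06, while the NMD factor gene UPF2 fell by 1.75. The NMD call was lost without pladienolide B replicate 2 (adjusted p = 0.0578) or 3 (0.0549), with quantile normalisation (0.0759) and with a mean of at least 50 (0.0581). Among NMD targets 8 were higher and 6 lower with the same total.

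Of the matrix genes, 23 of 36 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.000664; adjusted p = 0.473 with an estimated correlation), and the call was lost with quantile normalisation (adjusted p = 0.510). The median of 0.59 was 0.11 with the same total, where 13 matrix genes were higher and 12 lower. SNAI2, a repressor of epithelial genes, rose by 1.71. Of the chaperone genes, 14 of 20 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.00413, adjusted p = 0.473 with an estimated correlation), but the median of 0.34 was −0.13 with the same total and 0.01 with quantile normalisation, and the call was lost with both. Among chaperone genes 4 were higher and 8 lower with the same total. HSPA6 rose by 1.11.

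Of the mitotic genes, 36 of 54 fell and 7 rose, the same adjusted over the list alone (median −0.48, camera adjusted p = 0.000199; adjusted p = 0.577 with an estimated correlation). CDCA8 and NDC80, of the centromere and kinetochore, fell by 2.22 and 1.99 on the log2 scale. Of the homologous recombination genes, 24 of 36 fell and 4 rose, the same adjusted over the list alone (median −0.61, camera adjusted p = 0.000664; adjusted p = 0.473 with an estimated correlation). MUS81 fell by 1.98 and BRCA2 by 1.65. The lower genes numbered 49 mitotic and 30 homologous recombination genes with the same total.

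The other lists did not pass camera with pladienolide B. Of the replication genes, 17 of 39 rose and 16 fell (18 and 16 adjusted over the list alone), with a median of 0.10, a mean of −0.20 and opposite directions in camera and fry; the median was −0.38 with the same total, where 5 were higher and 24 lower. TK1 rose by 0.74 and CCNE2, a cyclin of S phase entry, fell by 1.84 on the log2 scale. Of the checkpoint genes, 5 of 22 rose and 13 fell, with RNF168 at 1.55 and CDC25C at −1.86. Of the excision repair genes, 6 of 23 rose and 13 fell, with the glycosylase gene NEIL3 at −3.50 and XPC at −2.11, and the list passed with the same total (adjusted p = 0.0219) and without the filter (0.0176). Of the p53 targets, 7 of 28 rose and 14 fell, with PLK2 at 1.96 and SESN1 at −2.12. Of the apoptosis genes, 9 of 27 rose and 16 fell, with BCL2L1 at 0.99 and BAK1, a pore-forming member, at −2.38. MCL1 fell to 21682 ± 514 (−0.44 ± 0.05, limma adjusted p = 9.69e-07).

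Of the stress response genes, 15 of 29 rose and 8 fell (16 and 8 adjusted over the list alone), with the chaperone gene HSPA5 at 1.34 and CEBPG at −1.90. That list passed without DMSO replicate 2 (adjusted p = 0.0342) or pladienolide B replicate 1 (0.0378), with the same total (0.0424) and without the filter (0.0183). The median of 0.55 was 0.08 with the same total, where 10 were higher and 10 lower. Of the MAPK genes, 11 of 21 rose and 6 fell, with SPRY2 at 2.28 and ETV5 at −1.59, and the median of 0.19 was −0.28 with the same total. Of the NF-kB genes, 7 of 23 rose and 6 fell, with IL6 at 2.00 and NFKB2 at −1.24; the median of 0.39 was −0.08 with the same total. Of the interferon genes, 10 of 25 rose and 4 fell, with IFI27 at 1.04 and IRF1 at −1.44, and the median of 0.04 was −0.41 with the same total. Of the cholesterol genes, 9 of 23 rose and 8 fell, with FDPS at 0.63 and STARD4 at −1.40, and the median of 0.04 was −0.44 with the same total. Of the glycolysis and hypoxia genes, 18 of 29 rose and 7 fell, with ADM at 1.55 and PFKFB4 at −2.96, and the median of 0.43 was −0.04 with the same total. It passed without DMSO replicate 1 (adjusted p = 0.0381), DMSO replicate 2 (0.0342) or pladienolide B replicate 3 (0.0139), and without the filter (0.0183). Of the ribosome biogenesis genes, 7 of 29 rose and 11 fell, with GNL3 at −1.11, and the list passed with quantile normalisation (adjusted p = 0.0253). Of the luminal genes 8 of 13 rose and 4 fell, with GATA3 at 1.96 and MLPH at −2.05, but 4 were higher and 6 lower with the same total. Of 8 leukocyte genes 2 rose, with CD68, a lysosomal protein gene, at 0.92. Counts that turned to more lower than higher with the same total were those of the SF3b (7 higher and 10 lower), ligase (1 and 7), SR protein (10 and 12), MAPK (7 and 12), NF-kB (5 and 7), interferon (4 and 10), cholesterol (1 and 13) and glycolysis lists (11 and 12), besides the replication, luminal and chaperone lists. The counts of the checkpoint, excision repair, p53, apoptosis, MAPK, NF-kB, interferon, cholesterol, glycolysis, biogenesis, luminal and leukocyte lists were the same when adjusted over the list alone.

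Several of the largest rises with pladienolide B were in features within other genes. The small nucleolar RNA (snoRNA) feature SNORD15B lies in RPS3 and rose from 16.4 ± 9.39 to 503 ± 16.1 (5.06 ± 0.51, limma adjusted p = 7.77e-07). SNORD16, within RPL4, rose by 4.70. FBXW4P1, within BCR, rose by 6.21. HOXD3, a homeobox gene, fell from 196 ± 24.8 to 3.54 ± 3.83, near the floor of 3 reads, so no fold is given. The largest falls included C5orf34 (−4.20 ± 0.21) and ZNF653, a zinc finger gene (−3.82 ± 0.13). PCF11, a factor of transcript cleavage, fell as well (−3.67 ± 0.21).

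**Figure D2:**
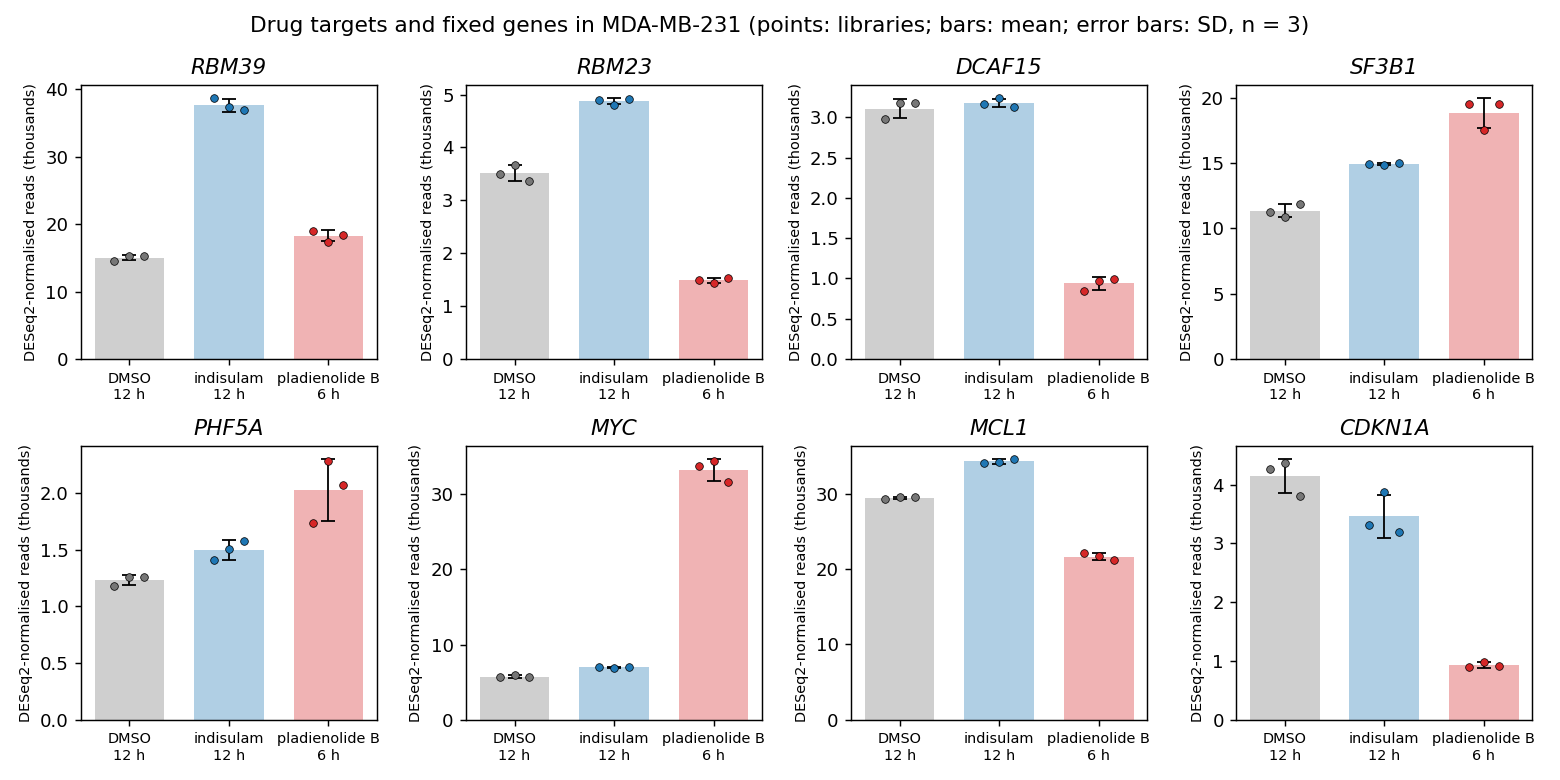
DESeq2-normalised reads (divided as the axes state) of the genes fixed before the data were examined, with points for libraries, bars for means and error bars for the SD (n = 3); axes start at 0. RBM39 was highest with indisulam (37646) and MYC with pladienolide B (33215); the rise of RBM39 with pladienolide B turned to −0.19 with the same total per library and −0.13 with quantile normalisation, and that of SF3B1 over indisulam to −0.09 and −0.05.

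The direct comparison of pladienolide B with indisulam asked where the responses differed, at unequal times. MYC was 4.76-fold higher with pladienolide B (2.25 ± 0.05, limma adjusted p = 1.06e-11). RBM39 was lower (−1.04 ± 0.05, adjusted p = 1.01e-09), as were RBM23 (−1.71 ± 0.06), DCAF15 (−1.76 ± 0.07), CDKN1A (−1.89 ± 0.09) and MCL1 (−0.66 ± 0.05). SF3B1 was at 0.33 ± 0.06, but at −0.09 with the same total and −0.05 with quantile normalisation, and PHF5A at 0.43 ± 0.10 was at 0.01 with the same total, where its call was lost. In all 5842 genes were higher and 5997 lower with pladienolide B, 1401 and 3107 of them at least 2-fold (4508 together, against 2941 among protein-coding symbols). With the same total per library 3014 were higher and 8497 lower, as the median of all genes moved by −0.41. Over all genes tested the values did not overlap in 12102 (71.8%), against 10% by chance.

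All 54 ribosomal protein genes (camera adjusted p = 2.03e-20), 27 of 34 histone genes (0.00108) and 25 of 36 matrix genes (0.00119; 5 lower) were higher with pladienolide B than with indisulam, with the same counts adjusted over the list alone. Each list had an adjusted p = 0.666 with an estimated correlation, and the matrix call was lost with quantile normalisation (0.323). The counts with the same total were 54 ribosomal protein and 12 histone genes higher, and 15 matrix genes higher and 9 lower. Histone values here too cover polyadenylated transcripts alone. Of the hnRNPs 14 of 19 were higher and 2 lower (camera adjusted p = 0.00512, adjusted p = 0.666 with an estimated correlation), with a median of 0.43 that was −0.02 with quantile normalisation. That call was lost with quantile normalisation (adjusted p = 0.576) and with the same total (0.1085), where 5 were higher and 6 lower. Of the immediate early genes 22 of 32 were higher and 6 lower (camera adjusted p = 0.0126, adjusted p = 0.666 with an estimated correlation), and of the intronless genes 20 of 35 and 7 (camera adjusted p = 0.0286, adjusted p = 0.666 with an estimated correlation), the latter with a median of 0.36 that was −0.06 with the same total. The intronless call was lost without pladienolide B replicate 2 (adjusted p = 0.0589), with quantile normalisation (0.167) and with the same total (0.101), where 12 were higher and 15 lower. The immediate early call was lost with quantile normalisation (adjusted p = 0.0857), and with the same total 11 of these genes were higher and 7 lower. Of the homologous recombination genes 23 of 36 were lower and 7 higher (camera adjusted p = 0.0137, adjusted p = 0.666 with an estimated correlation), and of the mitotic genes 31 of 54 and 12 (camera adjusted p = 0.0126, adjusted p = 0.697 with an estimated correlation). The homologous recombination call was lost with quantile normalisation (adjusted p = 0.143). The counts of these 5 lists were the same adjusted over the list alone. The other lists did not pass. The stress response list passed without indisulam replicate 2 (adjusted p = 0.04999) or 3 (0.0472) or pladienolide B replicate 1 (0.0340) or 3 (0.0471), with the same total (0.0460) and without the filter (0.0177). The interferon (0.0471) and glycolysis (0.0233) lists passed without pladienolide B replicate 3, and the glycolysis list also without the filter (0.0369). TRIM68, a ubiquitin ligase (−3.99 ± 0.12), and PDE7B, a phosphodiesterase (−3.74 ± 0.25), were among the genes with the largest difference.

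**Figure D3:**
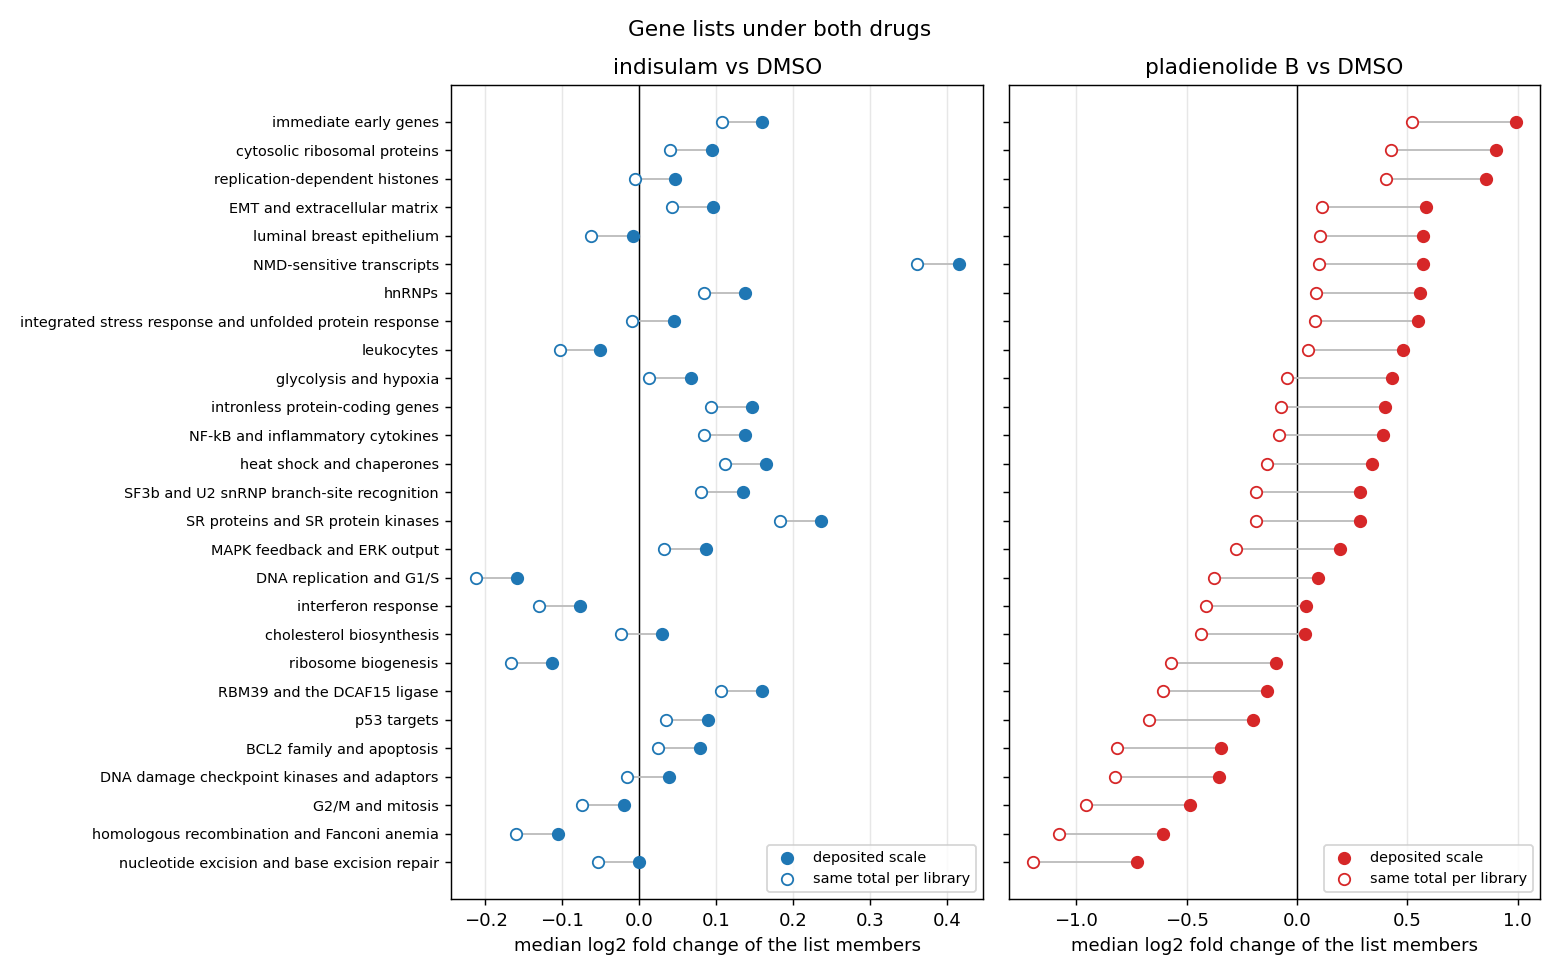
Median log2 fold change of the members of each gene list against DMSO, filled on the deposited scale and open with the same total per library. Ribosomal protein genes had a median of 0.90 with pladienolide B and 0.43 with the same total, while with pladienolide B the medians of chaperones, intronless genes, SR proteins, SF3b, MAPK, NF-kB, interferon, cholesterol, glycolysis and replication genes turned negative with the same total, as did those of checkpoint, stress response, cholesterol and histone genes with indisulam.

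With both drugs alike 1256 genes were higher and 978 lower than in DMSO. Independent lists of these sizes would share 836 and 743, and part of the overlap may come from the shared DMSO libraries. Simulated unchanged groups set against the same 3 DMSO libraries shared 0.05 and 0.03 on average, but as they had only 0.25 and 0.22 higher genes on average, that overlap could not be large. The covariance of the log2 fold changes over genes was 0.183, against 0.0368 in the simulations. The correlation across genes was 0.32, against 0.50 in the simulations, and genes are not independent replicates. Unchanged groups of equal size that share 1 control give about 0.50 by design. The lower observed correlation thus does not show that the drugs agree less than unchanged groups would. With the same total per library 603 genes were higher and 1882 lower with both. On the deposited scale a further 1172 genes changed in opposite directions, fewer than independent lists would give. Of these, 688 rose with indisulam and fell with pladienolide B (865 in independent lists), and 484 did the reverse (718).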

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

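Tests with protein-coding genes alone were chosen after the data were seen; the table gives no biotype, so the planned restriction was not run as written. Of the named genes called, 81 of 109 with indisulam and 106 of 121 with pladienolide B kept call and direction wherever tested. Between the drugs 18 of 20 did. There were 22 alternatives, but not every gene was tested in all of them. With protein-coding symbols alone 98, 107 and 13 of the named genes, called or not, were tested, in the same order. Of the 28 calls lost with indisulam, 26 were lost without 1 library. Of the list calls, 5 of 11, 6 of 10 and 3 of 8 kept theirs in 17 alternatives, which leave out the estimated correlation; with it 0 lists were higher and 0 lower in each comparison. With quantile normalisation 4 lists were higher with indisulam, 4 with pladienolide B, and 2 higher and 1 lower between the drugs; with the same total 5 were higher with indisulam. The cause of these list changes was not tested.

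With the same total per library 2733 genes were higher and 9086 lower with pladienolide B, 3014 were higher than with indisulam, and 603 and 1882 were higher and lower with both drugs. The rescaling moved the median of all genes by −0.47 and −0.41, which shows the cause. Genes changed at least 2-fold with indisulam numbered 381 with a mean of at least 50 and 212 among protein-coding genes. Among protein-coding genes 2931 and 2941 changed in the other comparisons. Fewer genes were tested in these alternatives. That alone does not account for the 212, since 12405 of the 16846 genes tested matched protein-coding genes of GENCODE. With the replicate number as a block 6287 genes were called with indisulam (4532 without it), 12329 with pladienolide B and 12399 between the drugs, 1926 were higher with both drugs (1256 without it), the mitotic list with indisulam was lost (adjusted p = 0.0583), and the stress response and glycolysis lists passed with pladienolide B (0.0346 and 0.0232) and between the drugs (0.0333 for both); the cause was not tested. Correlations of same-numbered libraries ran from 0.00266 to 0.128, and as not all were over 0.1 the numbers were not taken as pairs. Each of the 9 libraries was on average closest to its own number, and the highest correlation of different numbers was 0.045, a hint of pairs from the data and not from the design. edgeR and DESeq2 called 4716 and 5222 genes with indisulam, and shared 4486 and 4521 with limma in direction.

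Without 1 library the genes higher with indisulam ranged from 1565 (without indisulam replicate 3) to 2982 (without pladienolide B replicate 2), with 1620 without DMSO replicate 2. Those lower ranged from 1489 to 2386. Leaving out a pladienolide B library does not change the fold changes of indisulam against DMSO. The 2982 can thus come only through the spread, which was estimated over all 3 groups together. The cause of the other changes was not tested. With pladienolide B the ranges were 5403 to 5735 higher and 5581 to 5967 lower.

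The following signs reversed, and the cause was not tested beyond the shifts above. With pladienolide B and the same total, RBM39 was at −0.19, RAD51C at −0.11, FANCB at −0.20, CDK1 at −0.043 and PTTG1 at −0.12. With quantile normalisation RBM39 was at −0.13, PTTG1 at −0.0079, HSPB8 at 0.042, NPM1 at −0.063 and the chaperone list at 0.013, where camera gave the lower direction. Between the drugs SF3B1 was at −0.086 with the same total and −0.048 with quantile normalisation, and the hnRNP list at −0.017 with the latter. Genes near the minimum mean of 10 stand only a few times above the floor of 3 reads.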

Other observations

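The tests of scaling, of lost new transcripts, of time and of other splits of the libraries were chosen only after the results were seen, and the genes named next were chosen after their values were seen. Among genes that rose with indisulam and fell with pladienolide B were AGO4, an Argonaute protein gene (1.03 and −0.97), PRKAB1, a subunit of AMP-activated kinase (0.96 and −1.44), the zinc finger gene ZNF512 (0.94 and −1.03), and PLEKHA7, of adherens junctions (0.90 and −1.96). POLA1, the catalytic subunit of DNA polymerase alpha, fell with indisulam (−0.82) and rose with pladienolide B (0.69), as did TOMM34, a mitochondrial import factor gene (−0.63 and 0.66). These signs were the same with the same total per library, where POLA1 stood at 0.22 and TOMM34 at 0.19 with pladienolide B.

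Genes with more introns stood lower with both drugs. Across 12126 genes with introns, the median with pladienolide B was 0.16 in the 3032 genes with the fewest introns and −0.33 in the 3032 with the most, and 0.11 and −0.08 with indisulam (0.05 and −0.13 with the same total; −0.30 and −0.80 with pladienolide B). Spearman's rho across genes, which are not independent replicates, was −0.194 with pladienolide B and −0.226 with indisulam for intron number, and −0.212 and −0.057 for total intron length. For transcript length it was −0.242 and −0.00506, and the median with pladienolide B was 0.32 in the 3032 shortest transcripts and −0.33 in the 3032 longest. It was −0.154 with indisulam for transcript GC content and 0.211 with pladienolide B for the mean in DMSO. The pattern is thus not shown to be particular to introns with either drug, and intron number was not tested apart from these properties.

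Of 93 snoRNA features tested, 83 were higher and 2 lower with pladienolide B (median 2.77, and 2.33 with the same total). With indisulam 17 were higher and 0 lower in limma. Features were tested on their mean over all 9 libraries, so a snoRNA near the floor in the other groups entered only through pladienolide B. The share, the medians and the difference from the host below are thus partly set by this filter. Higher measured levels of the host genes are argued against as the whole cause in the 44 features with a tested host. There snoRNA minus host had a median of 2.62, 42 features were above their host, and the host median was 0.37. A permutation test of signs gave p = 2e-05, the smallest the resamples can give. It took features as independent, although some share a host and all come from the same libraries. That p-value does not measure the spread between libraries, and host transcription was not measured. Reads from retained host introns may add to these features. Pseudogene features inside introns stood 1.10 higher on the host's strand (14 features) than on the opposite strand (7), with an exact permutation p of 0.135. With so few features, and the strand setting of the counts not given, intron reads and mature snoRNAs cannot be told apart. The libraries were made from polyadenylated RNA, so the values do not measure snoRNAs without a poly(A) tail.

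Single-exon protein-coding genes other than histones stood above genes with introns with pladienolide B: 178 of 279 rose and 37 fell. Transcript length, GC content and expression are argued against as the whole cause, since the median of 0.67 lay 0.78 above that of multi-exon sets matched on them, and above all 10000 sets. With indisulam the difference was 0.22, and the median of 0.22 there also lay above all 10000 sets. With the same total per library the median of the single-exon genes with pladienolide B was 0.20. Whether transcripts made without splicing escape the drug stays open, since the direct effect on splicing was not measured here. The difference of 0.776 with the same total per library decides nothing, as that scaling moves both classes nearly alike.

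Ribosomal protein and mitochondrial features were higher with pladienolide B. A scaling that raises every gene alike is argued against as the whole cause for the ribosomal protein genes, as 54 of 54 stayed higher with the same total per library. The mitochondrial median went from 1.09 to 0.62 on that scale, where 11 of 15 features stayed higher. The size of the rise thus depends on the scaling. Loss of new transcripts of all genes, leaving long-lived ones, is argued against by the immediate early genes, whose transcripts are short-lived: on that scale 16 of 32 were called higher and 7 lower, with a median of 0.52. These values were known when the test was chosen, and they cover the immediate early genes alone. Loss in some genes stays open. The 2733 higher and 9086 lower genes on that scale cannot decide it, as the rescaling itself moved the median of all genes by −0.47. The DMSO libraries were of 12 h and the pladienolide B libraries of 6 h, so time and drug cannot be told apart, and time may contribute.

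Of the 10 splits of the 6 libraries of each comparison into 3 and 3, 1 gave as many genes as the real one, the real split itself, so the share cannot fall under 0.05. The real splits gave 4532 genes for indisulam, 11752 for pladienolide B and 11839 between the drugs, and the highest of the other splits gave 1, 0 and 0.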
